A study of Mus musculus with 6 samples.

How the data were processed

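RNA was sequenced from mouse embryonic stem cells of the MPI-II line, with an intact Ddx5 gene or after its disruption. Per the labels' protocols, both kinds of cells grew on feeder cells in medium with serum, leukemia inhibitory factor, the MEK inhibitor PD0325901 and a GSK3 inhibitor. The knockout (KO) lines were made with a Cas9 nickase and a pair of guide RNAs against the second exon of Ddx5, selected with G418 and grown from single clones. RNA was extracted with TRIzol, per the labels' protocols. The labels give 2 wild-type (WT) libraries, numbered as replicates, and 4 KO libraries, numbered as lines, while the design text of the series speaks of triplicates. Nothing in the labels says that the 2 WT replicates came from separate cultures. The genes of chromosome 8 stood higher in WT replicate 2 than in WT replicate 1 (median log2 0.48, 603 genes). This argues against 2 libraries of the same RNA. The p-values measure the spread between these samples, and how independently the WT cells were grown is unknown. The test pools 1 variance per gene over both groups, with 4 residual degrees of freedom, most of them from the KO lines. The 2 WT libraries correlated less with each other (r = 0.934) than the KO lines did (0.967 to 0.990). Where WT varied more than KO, p-values from the pooled variance can be too small.

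The submitters' processing notes name RSEM 1.2.17, Bowtie2 2.2.0 and the mouse genome build mm10. The role of each tool, the gene annotation and the normalization step are not given in the sources used here. The deposited table holds 1 value per gene and library for 10989 genes, and the authors named its unit CPM. The values contradict that name. They are whole numbers that sum to between 14612799 and 14722877 per library, the highest value, 78894, is shared by 10 genes in each of the 6 libraries, and the next steps are as coarse (36416 to 36468, then 29804 to 29876). Sorted, the values lay within 1% of the median library at 92.0% to 93.3% of ranks in the KO lines, 79.9% in WT replicate 1 and 51.2% in WT replicate 2. Quantile normalization gives such a shape, less closely met by WT replicate 2, and each gene reaches 80 in at least 2 libraries. The deposited values were therefore treated as a normalized score with no fixed unit, and are given below in deposited units. Read counts cannot be recovered from them, so the depth of each library is unknown and no counting interval is given. A change in the total RNA of a library, or in the shape of its distribution, is not visible in such values, and differences between the most abundant genes are compressed into a few steps.

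Genes were matched by symbol and identifier to GENCODE M21 (build mm10), which gave a position, GC content and transcript length for 10941 genes. Of the symbols, 10 stood on 2 rows and were kept as separate genes. Levels were divided by 14.7 deposited units, the mean library total over 1000000, to give scaled values. The test had been fixed for CPM, and this scale was chosen from the shape of the values, before any test was run. A pseudocount of 1 was added to the scaled value and log2 taken. Log2 fold changes are on this scale, which understates the change of low genes, while rises written as N-fold are ratios of mean deposited values without a pseudocount. Counts of genes changed at least 2-fold use a log2 fold change of at least 1 in size. Genes needed a scaled value of at least 1 in at least 2 libraries, which removed none. KO and WT were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with a mean-variance trend, two-sided, on all 6 libraries and with no covariate. p-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p below 0.05. Adjusted p-values for genes come from this limma fit throughout. An exact permutation of 2 against 4 libraries cannot give a p below 0.0667.

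Before the data were examined, 22 gene lists, the test, the rule for named genes, and the alternatives were fixed. The lists cover Ddx5 and microRNA processing, non-canonical PRC1, canonical PRC1, PRC2, naive pluripotency, formative and primed pluripotency, mesoderm and primitive streak, endoderm, neural ectoderm, trophoblast, germ line, 2-cell stage, feeder fibroblast, p53 targets, ERK signalling targets, Wnt targets, Hox, imprinted, sex chromosome, interferon response, ribosome biogenesis, and glycolysis and hypoxia. The 19 lists with at least 5 measured members were tested with camera from limma with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. List p-values were adjusted over the lists. Named genes were chosen in 3 parts. The first is Ddx5, Ddx17 and Rybp. The second is the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with all 4 KO lines on one side of both WT libraries and a group mean of at least 5 in scaled values, predicted genes (Gm numbers, Rik names) skipped. The third is up to 4 called members per list with the largest fold change, or the member with the largest fold change where none was called. Genes outside this rule are marked as chosen after their values were seen.

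The fit was tested on simulated data for the KO against WT comparison, with 10989 genes, in 5 simulations. In each, 200 genes were changed singly and a planted list of 20 more together. The fit recovered 55.4% of 2-fold and 82.0% of 4-fold changes among the 200, and 5.34% of the calls were false. The planted list was found in 5 of 5 simulations against 0 of 5 for an unchanged list. Simulated noise was independent between genes, so these runs do not show how camera treats lists of correlated genes. It also had the same SD in WT and KO libraries. The real WT libraries correlated less with each other (r = 0.934) than the KO lines did (0.967 to 0.990). The share of false calls in the real data may therefore differ from the simulated one. Alternatives were other pseudocounts and filters, trimmed-mean scaling, quantile normalization, other variance models, the replicate number as a block, and leaving out each library. Added after the data were seen were a pseudocount of 1 deposited unit, a mean of at least 200 deposited units, the level of the feeder fibroblast list as a covariate, and a fit without the genes of chromosomes 6 and 8. Chromosome levels were computed as the median log2 difference from WT replicate 1 over the genes of a chromosome minus that over all other genes, with 95% intervals from 1000 bootstrap draws of genes. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.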

Results

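Gene expression was measured by RNA sequencing in mouse embryonic stem cells of the MPI-II line, in 2 wild-type (WT) libraries and in 4 separately cloned lines in which Ddx5 had been disrupted (KO). Ddx5 encodes an RNA helicase, also known as p68, that works in splicing, transcription and microRNA processing. The title of the series names lineage genes and Polycomb repressive complexes, protein complexes that keep developmental genes silent. The comparison of KO with WT addressed which of these and other genes differ when Ddx5 is lost. Values are normalized expression scores in deposited units for 10989 genes. Library totals lay between 14612799 and 14722877 units. They result from the normalization and say nothing of sequencing depth, which is unknown. WT replicate 2 stood apart, with 131 genes at 0 against 13 to 19 in the other libraries. Across genes, the log levels of the KO lines correlated with each other at r of 0.967 to 0.990, the 2 WT libraries at 0.934, and KO with WT libraries at 0.890 to 0.932. Genes are not independent replicates.

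Ddx5 transcript fell in each KO line. The gene (ENSMUSG00000020719, chromosome 11, 106780355 to 106789185 on the minus strand, build mm10) stood at 36433 and 36436 units in the WT libraries. It stood at 5854, 8450, 12793 and 5659 units in KO lines 1 to 4, a mean of 8189 ± 3323 (SD, n = 4). The log2 fold change was -2.23 (SE 0.317, adjusted p = 0.00807, limma), with the 4 lines below both WT libraries. The WT values lie on the second highest step of the table, where levels are compressed, so the size of the fall is approximate. Its paralog Ddx17, an RNA helicase with overlapping functions (ENSMUSG00000055065, chromosome 15, 79527736 to 79546741), rose 2.41-fold. It went from 4395 and 4742 units to a mean of 11032 ± 879 (SD, n = 4), a log2 change of 1.27 (SE 0.0955, adjusted p = 0.00201). Both calls held with each library left out in turn. Rybp, a subunit of non-canonical Polycomb repressive complex 1 (PRC1), lay at 4048 ± 260 units (SD, n = 2) in WT and at 5335, 5049, 5117 and 7682 units in the KO lines. Its difference did not pass the test over all lines (log2 0.49, SE 0.179, adjusted p = 0.0974). Without KO line 4, in which the genes of chromosome 6 as a whole stood higher, Rybp did pass, with a log2 change of 0.35 (adjusted p = 0.0464), and without any other single library it did not (adjusted p up to 0.274).

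**Figure D1:**
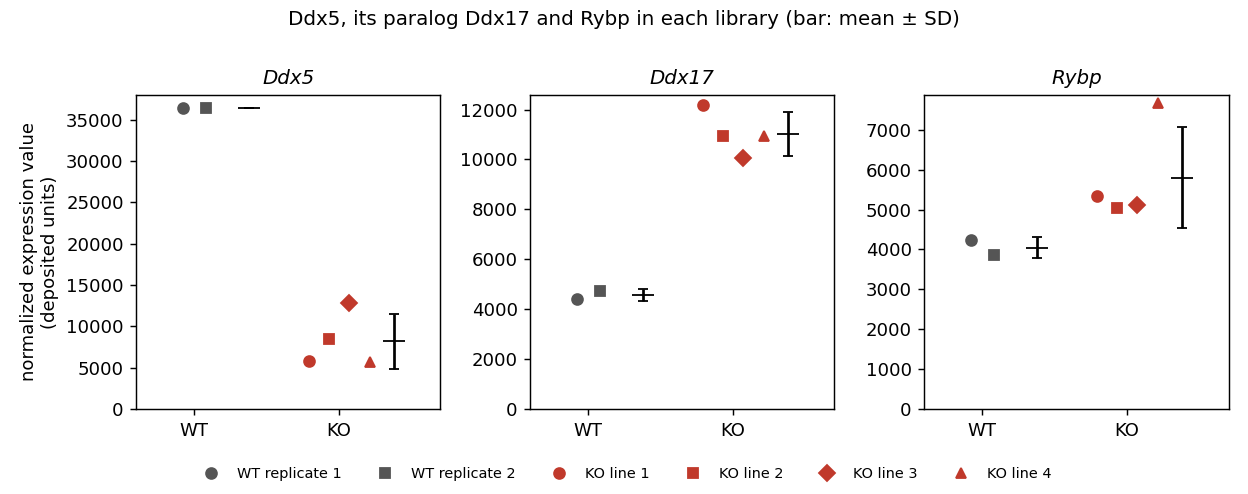
Levels of Ddx5, Ddx17 and Rybp (vertical axes, deposited units, from 0) in the 2 WT libraries (grey) and the 4 KO lines (red), with mean and SD beside them. Ddx5 lies at 36433 and 36436 in WT and between 5659 and 12793 in the KO lines, Ddx17 is higher in all 4 lines, and KO line 4 stands apart at 7682 for Rybp.

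Loss of Ddx5 was accompanied by higher germ line and glycolysis and hypoxia genes and by lower fibroblast, ERK signalling and Wnt target genes. These 5 lists passed with camera at its preset correlation, and none held with an estimated one (adjusted p = 0.0935 to 0.801 with an estimated correlation). The estimates were 0.69 for fibroblast, 0.60 for glycolysis and hypoxia, 0.05 for ERK, and -0.05 for germ line and Wnt genes. For germ line and Wnt genes they lay below the preset 0.01, so a higher correlation does not account for the loss there. In all, 1878 of the 10989 genes passed the test, 1071 of them higher and 807 lower in the KO lines, and 721 differed at least 2-fold, 414 higher and 307 lower. Each of the 1878 had its 4 KO lines on one side of both WT libraries. The test itself favours such genes, so this is not separate evidence of agreement among the lines. Of all genes, 43.7% had their KO lines on one side, where chance gives 13.3%. The number of calls depended on the libraries used. It was 472 without KO line 2, 572 without KO line 3, 1223 without KO line 1 and 3304 without WT replicate 1. Genes at least 2-fold changed numbered 331 without KO line 2, 377 without KO line 3 and 1293 without WT replicate 1. Higher genes did not outnumber lower ones in every fit. With trimmed-mean scaling 959 genes were higher and 967 lower. Among those at least 2-fold changed, 300 were higher and 339 lower with quantile normalization, 211 and 225 with a pseudocount of 5, 155 and 176 without KO line 2, and 185 and 192 without KO line 3. With the replicate number as a block, 2 genes were higher and 18 lower. Among the 63 called genes named here, 23 lost the call with at least 1 library left out and 40 passed in each such fit that tested them. Of these 40, Col6a1, Col6a2, Cxcl1 and Tnfaip2 were tested in 4 of the 6 fits, since with 1 WT library they did not reach the level required.

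Genes typical of fibroblasts were the lowest group in the KO lines. Collagen subunits of the connective tissue matrix led it. Col1a2, a chain of type I collagen, lay at 9391 and 3548 units in WT and at 294 ± 110 (SD, n = 4) in the KO lines, a log2 change of -4.30 (SE 0.443, adjusted p = 0.0038). Col6a1, a chain of type VI collagen, went from 714 ± 337 (SD, n = 2) to 6 ± 2.31 (SD, n = 4) units. Its log2 change, -5.06, was the largest fall among the named genes, followed within the list by Col6a2 at -4.57. The chemokine gene Ccl2 fell by 3.61. Of the 18 measured members of the feeder fibroblast list, 16 fell and 2 did not pass (17 lower when adjusted over the list alone), with a median log2 change of -2.72. The list passed with camera (adjusted p = 4.21e-14) and not when the correlation was estimated (adjusted p = 0.35 with an estimated correlation). The cells had been grown on feeder cells, and the mean log2 level of the list was 6.69 in WT replicate 1, 5.69 in WT replicate 2 and 3.08 to 3.72 in the KO lines.

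Among the other genes with the largest falls, the metalloproteinase inhibitors Timp2 and Timp3 had log2 changes of -4.26 and -4.20, and the matrix proteins fibulin (Fbln2) and thrombospondin (Thbs1) of -4.60 and -4.19. The chemokine Cxcl1 (-4.59), the growth factor Igf2 (-4.82) and Tnfaip2 (-4.45), a gene induced by tumour necrosis factor, fell as far. Thbs1, the most abundant of them, went from 6898 ± 2790 (SD, n = 2) to 371 ± 157 (SD, n = 4) units. These genes were lower in the same lines as the fibroblast list. All 4 KO lines lay on one side of both WT libraries for every called gene. Sharing these lines, here and below, therefore does not show a shared source. Fbln2 and Col1a2 lie on chromosome 6, which stood higher in KO line 4.

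Germ line genes were higher in the KO lines. Mov10l1, a helicase of the piRNA pathway that silences transposons in germ cells, rose from 46 and 44 units to 340, 416, 371 and 566 units, a log2 change of 2.85 (SE 0.218, adjusted p = 0.00201). Piwil2, a piRNA-binding protein, rose by 2.14 from 42 ± 17 (SD, n = 2) to 236 ± 62.4 units (SD, n = 4). Stra8, which is needed for entry into meiosis, rose by 1.87, and Ddx4, the germ cell helicase also called Vasa, by 1.19. Of the 14 measured members of the germ line list, 11 rose, none fell and 3 did not pass (13 higher when adjusted over the list alone), with a median log2 change of 1.06. Camera gave an adjusted p of 1.19e-06, which was lost when the correlation was estimated (adjusted p = 0.0935 with an estimated correlation). The estimate, -0.05, lay below the preset 0.01, and camera run with an estimated correlation gave an unadjusted p of 0.00492. The list passed with camera whichever library was left out, but its higher members numbered 2 without KO line 3, 3 without KO line 2, and 7 without KO line 1 or WT replicate 2. Singly, the calls of Stra8 and Ddx4 were lost in 4 and 3 of the 6 fits with a library left out, with adjusted p up to 0.0707 and 0.0787, and Stra8 lies on chromosome 6.

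Other genes with the largest rises included RNA-binding proteins of germ cells. Boll, a member of the Dazl family, was listed at 0 in both WT libraries and at 236, 200, 152 and 204 units in the KO lines (adjusted p = 0.00181). Rbm46, which germ cells need for meiosis, went from 2 and 1 to 188 ± 15.2 units (SD, n = 4), and Rbm44, another RNA-binding protein of the germ line, from 24 and 0 to 159 ± 22.2 units (SD, n = 4). The X-linked gene Xlr3c rose by 3.63 but with a wide spread, from 62 and 2 to 594, 886, 506 and 120 units. It belongs to a family of near-identical copies among which reads may have been split, so its level is uncertain. Its call was lost in 4 of the 6 fits with a library left out (adjusted p up to 0.142). Further genes of this group were the kinesin Kif26a (log2 3.08) and the sulfotransferase Chst3 (2.86). The semaphorin Sema4g (2.84) and the arginine methyltransferase Prmt8 (2.81, on chromosome 6) belonged to it too. With a library left out, Kif26a lay between 2.45 and 3.71 and Chst3 between 2.35 and 3.36. Sema4g then lay between 2.02 and 3.66 and Prmt8 between 2.40 and 3.21. The synaptic adhesion gene Lrfn5 was listed at 0 in both WT libraries and at 44 to 162 units in the KO lines (call lost in 2 of the 6 fits with a library left out, adjusted p up to 0.0546).

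**Figure D2:**
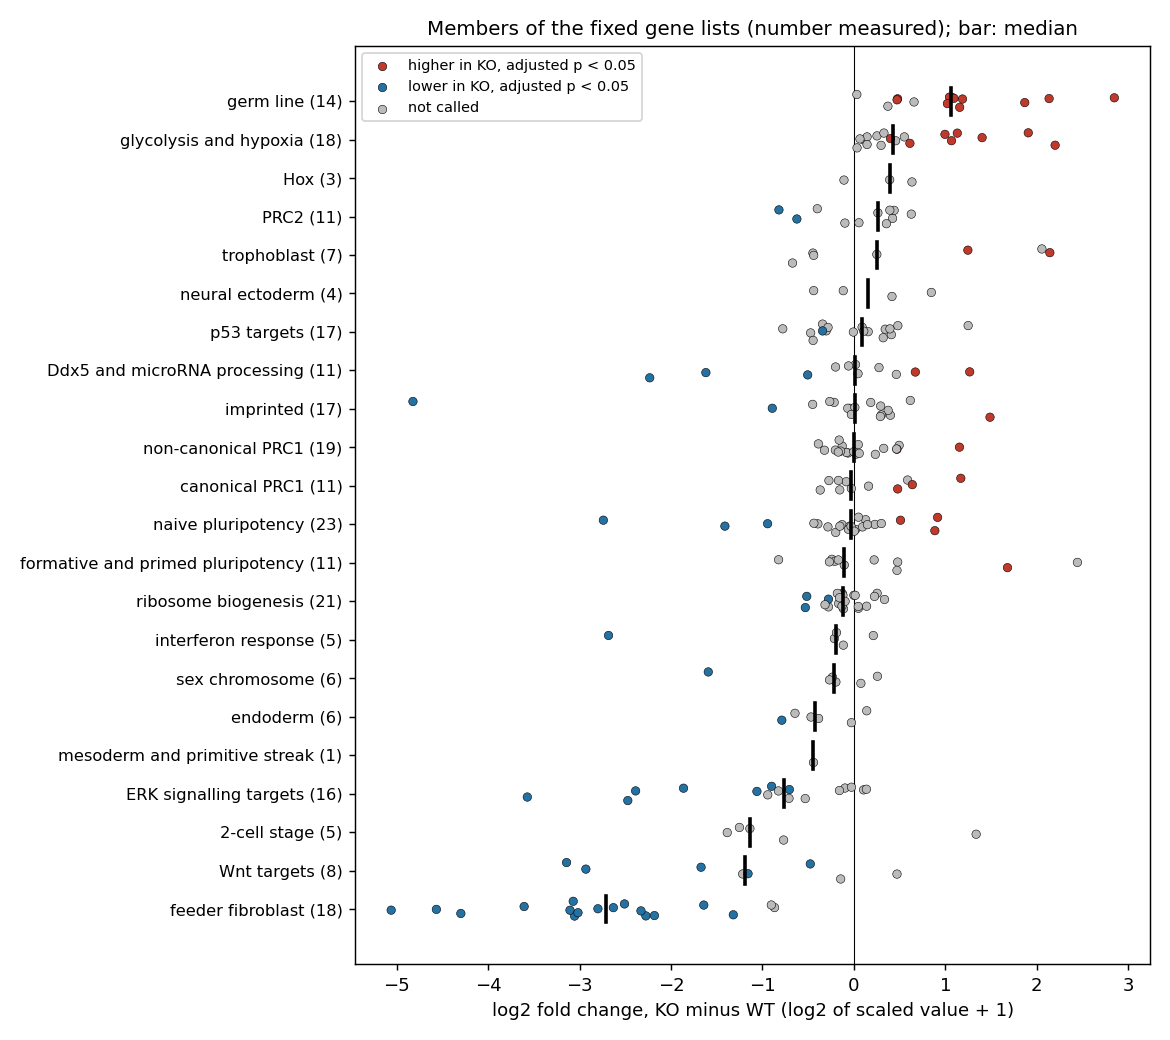
Log2 fold change, KO minus WT (horizontal axis, log2 of the scaled value plus 1), of each measured member of the 22 lists, 1 row per list with the number measured; red and blue points passed the test as higher and lower, grey points did not, and the bar is the list median. The germ line list has the highest median (1.06) and the feeder fibroblast list the lowest (-2.72).

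Targets of ERK signalling, the kinase cascade that the MEK inhibitor in the medium blocks, were lower in the KO lines. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, went from 527 ± 26.9 (SD, n = 2) to 33.0 ± 16.7 (SD, n = 4) units, a log2 change of -3.57 (SE 0.353, adjusted p = 0.00334). The phosphatase genes Dusp4 and Dusp5, which switch off kinases of this cascade, had log2 changes of -2.47 and -2.39, and the transcription factor Myc of -1.86. Of the 16 measured members of the list, 7 fell, none rose and 9 did not pass (7 lower also when adjusted over the list alone), with a median log2 change of -0.77. Camera gave an adjusted p of 0.000322 for the list, not held with an estimated correlation (adjusted p = 0.198 with an estimated correlation). Without WT replicate 1 the list did not pass (adjusted p = 0.102), and 2 members were called higher and 5 lower. Its lower members numbered 3 without KO line 2 and 4 without KO line 3. The call of Myc was lost with 5 of the 6 libraries left out singly, with adjusted p up to 0.136. Dusp4 lies on chromosome 8, which stood higher in 4 libraries, and the fibroblast genes were lower in the same lines.

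Targets of Wnt signalling were lower too. Sp5, a transcription factor induced by Wnt, went from 274 ± 108 (SD, n = 2) to 17.8 ± 9.18 (SD, n = 4) units, a log2 change of -3.14 (SE 0.41, adjusted p = 0.00694). Axin2, a negative feedback regulator of the pathway, fell by 1.67. The signalling protein Bmp4 had a log2 change of -2.93 and Notum, an enzyme that inactivates Wnt proteins, of -1.16. Of the 8 measured members, 5 fell, none rose and 3 did not pass (5 lower also when adjusted over the list alone); the median was -1.19. The list passed with camera (adjusted p = 0.000681) and not when the correlation was estimated (adjusted p = 0.162 with an estimated correlation). Its lower members numbered 2 without WT replicate 2 and 3 without KO line 2 or KO line 3. The calls of Bmp4 and Notum were lost in 1 and 3 of the 6 fits with a library left out, with adjusted p up to 0.0666 and 0.0626. These falls, too, ran in the same lines as those of the fibroblast genes.

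Part of the glycolysis and hypoxia list rose in the KO lines. Vegfa, the vascular growth factor, went from 421 ± 132 (SD, n = 2) to 1977 ± 420 (SD, n = 4) units, a 4.70-fold rise (log2 2.2, SE 0.244, adjusted p = 0.00472). Egln3, a prolyl hydroxylase that marks hypoxia-inducible factor for degradation, rose by 1.91, the mitophagy gene Bnip3 by 1.40 and Ndrg1, a stress-response gene, by 1.13. Of the 18 measured members of the glycolysis and hypoxia list, 8 rose, none fell and 10 did not pass (8 higher also when adjusted over the list alone), with a median log2 change of 0.43. The other 4 that rose, chosen after their values were seen, were the glycolytic enzymes Pfkp (log2 1.07), Gpi1 (0.61) and Pfkl (0.40) and the glucose transporter Slc2a1 (1.00). Camera gave an adjusted p of 0.00122, which was lost with an estimated correlation (adjusted p = 0.801 with an estimated correlation) and with fry (adjusted p = 0.107). The higher members numbered 2 without KO line 2, 3 without WT replicate 2 and 5 without KO line 1 or KO line 3. With a library left out, the call of Pfkl held in none of the 6 fits (adjusted p up to 0.121). Those of Bnip3, Ndrg1, Pfkp, Gpi1 and Slc2a1 were lost in 2, 4, 1, 3 and 5 of them, with adjusted p up to 0.0894, 0.114, 0.0569, 0.088 and 0.149. The fibroblast genes were lower in the same lines.

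**Figure D3:**
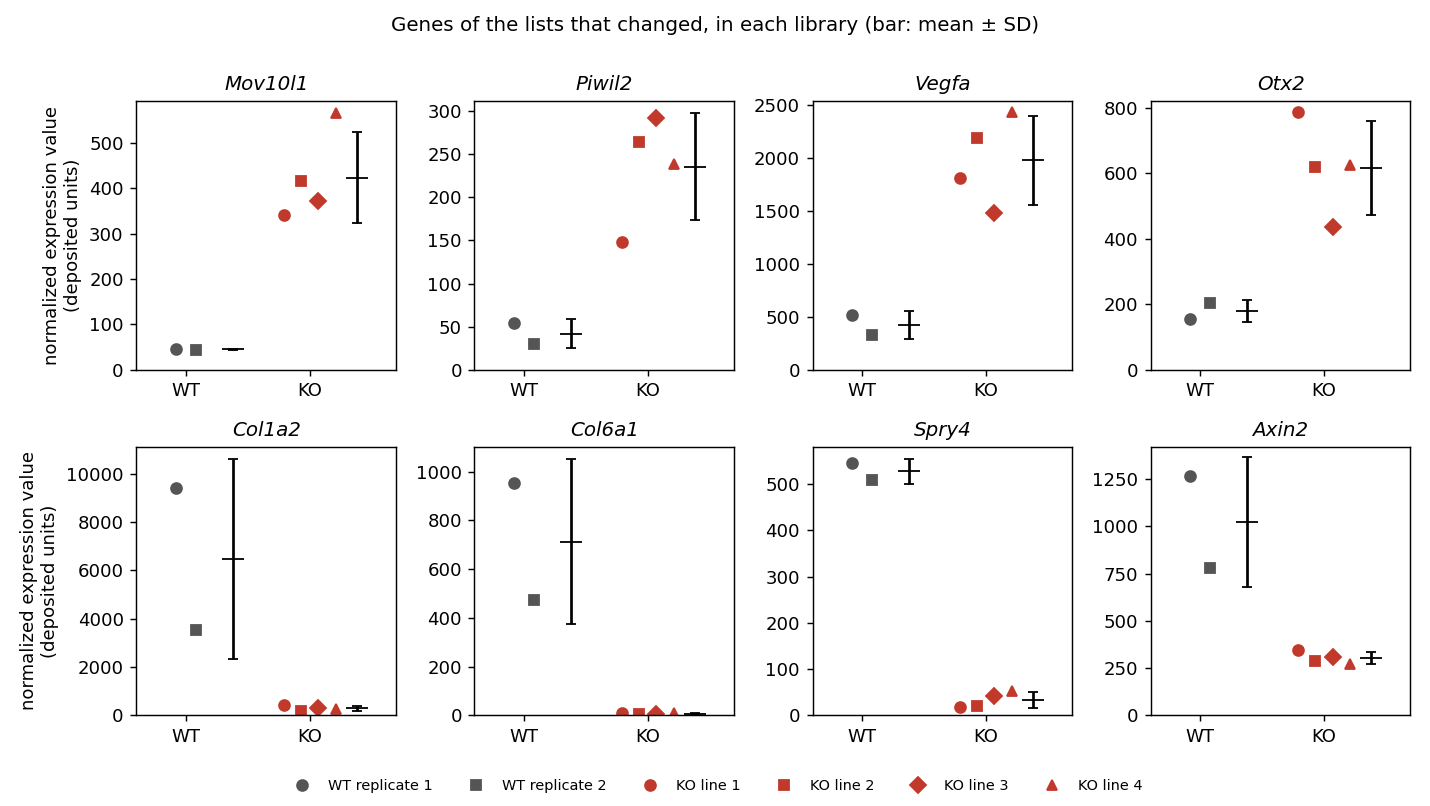
Levels (vertical axes, deposited units, from 0) of 8 genes from the lists in the 2 WT libraries (grey) and the 4 KO lines (red), with mean and SD beside them. Mov10l1, Piwil2, Vegfa and Otx2 are higher and Col1a2, Col6a1, Spry4 and Axin2 lower in all 4 lines than in both WT libraries.

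Pluripotency genes moved in both directions. Within the naive pluripotency list, Gbx2, a homeobox gene downstream of leukemia inhibitory factor, fell from 543 ± 94.8 (SD, n = 2) to 75 ± 38 (SD, n = 4) units (log2 -2.74, SE 0.43, adjusted p = 0.0107). The nuclear receptor Nr0b1 fell by 1.41 and the transcription factor Klf4 by 0.94, while Prdm14, a regulator of naive and germ cell identity, rose by 0.92. Nanog, a core pluripotency factor, and Dppa2, both chosen after their values were seen, rose by 0.89 and 0.51. Nanog lies on chromosome 6 and was still higher without KO line 4 (log2 0.78, adjusted p = 0.0186). Pou5f1, which encodes Oct4, likewise chosen after its values were seen, had a log2 change of 0.02 and did not pass. In all, 3 of the 23 measured members rose, 3 fell and 17 did not pass (4 higher and 3 lower when adjusted over the list alone), and the list did not pass with camera (adjusted p = 0.686; median -0.03). The calls of Nr0b1, Prdm14, Nanog and Dppa2 were lost in 3, 4, 2 and 5 of the 6 fits with a library left out, with adjusted p up to 0.0617, 0.0774, 0.0601 and 0.108.

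Among genes of later stages, the homeobox gene Otx2, which marks the exit from the naive state, rose 3.43-fold. It went from 180 ± 33.9 (SD, n = 2) to 617 ± 143 (SD, n = 4) units (log2 1.68, SE 0.234, adjusted p = 0.00767). It was the 1 called member of 11 in the formative and primed pluripotency list, also when adjusted over the list alone. The median of that list (-0.11) differs in sign from its mean (0.32) and from camera, which pointed up with an adjusted p of 0.887. In the trophoblast list, the transcription factors Tfap2c and Ascl2 rose by 1.25 and 2.14, Ascl2 from 35 and 1 to 112 ± 29.5 units (SD, n = 4). The other 5 of its 7 measured members did not pass (3 higher when adjusted over the list alone), nor did the list (adjusted p = 0.585). The calls of Tfap2c and Ascl2 were lost in 2 and 5 of the 6 fits with a library left out, with adjusted p up to 0.0565 and 0.0892. Of the 6 measured endoderm genes, only the matrix gene Sparc, which fibroblasts also express, was called, with a log2 change of -0.79, also when adjusted over the list alone. Its call was lost in 2 of the 6 fits with a library left out (adjusted p up to 0.0653), and the list did not pass (adjusted p = 0.241). In neural ectoderm none of 4 measured genes passed over all genes, against 1 higher and 1 lower when adjusted over the list alone. Sox1, a neural transcription factor on chromosome 8, had a log2 change of 0.85 (adjusted p = 0.0613) and passed without WT replicate 1 (adjusted p = 0.0196) but in none of the other 5 fits with a library left out (adjusted p up to 0.153). Mesoderm had 1 measured gene, Eomes, at -0.45 (adjusted p = 0.288), and of 3 Hox genes none passed, with Hoxc4 at 0.64 (adjusted p = 0.399). With a library left out, Eomes lay between -0.87 and -0.03, and Hoxc4 between -0.02 and 1.29. The counts of called mesoderm and Hox genes were 0 also when adjusted over the list alone. The neural, mesoderm and Hox lists were too short for a list test.

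Some Polycomb genes rose and others fell. Cbx2, a subunit of canonical PRC1 that binds methylated histone H3, rose 2.29-fold, from 390 ± 46.0 (SD, n = 2) to 892 ± 32.7 (SD, n = 4) units (log2 1.17, SE 0.11, adjusted p = 0.00326). Bcorl1, a subunit of non-canonical PRC1, rose 2.34-fold (log2 1.15, adjusted p = 0.0079). Scmh1 (0.64), Scml2 (0.48) and Pcgf3 (0.47) rose by less. Their calls were lost with 5 of the 6 libraries left out singly, with adjusted p up to 0.115, 0.124 and 0.102. In PRC2, the complex that methylates histone H3, the core subunit Eed fell by 0.62 and E130012A19Rik, an accessory subunit, by 0.82. The call of Eed was lost in 3 of the 6 fits with a library left out, with adjusted p up to 0.0807. Counted by list, 2 of 19 members of non-canonical PRC1 and 3 of 11 of canonical PRC1 rose and none fell, with the same counts when adjusted over the list alone. In PRC2, 2 of 11 members fell (3 higher and 2 lower when adjusted over the list alone). Of all 10989 genes, 1878 were called, so a few called members would occur in lists of this size at that share alone. None of the 3 lists passed with camera (adjusted p = 0.887, 0.6 and 0.887). For both PRC1 lists the median (-0.00193 and -0.03) differs in sign from the mean (0.09 and 0.18) and from camera, which pointed up.

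In the Ddx5 and microRNA processing list, Lin28a, which blocks maturation of the let-7 microRNAs, fell from 2136 ± 220 (SD, n = 2) to 699 ± 178 (SD, n = 4) units (log2 -1.62, SE 0.219, adjusted p = 0.00753). Ago1, a microRNA effector, rose by 0.67. With Ddx5 and Ddx17, 2 of the 11 measured members rose and 3 fell (3 and 3 when adjusted over the list alone). The list did not pass (adjusted p = 0.887), and its median, 0.02, differs in sign from its mean, -0.17, and from camera, which pointed down.

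The remaining lists did not pass with camera. Among imprinted genes, the growth factor Igf2 and the translation regulator Impact fell, with log2 changes of -4.82 and -0.89, and Peg12 rose by 1.49. That made 1 higher and 2 lower of 17, with the same counts when adjusted over the list alone (list adjusted p = 0.887). The median of the list (0.01) differs in sign from its mean (-0.17) and from camera, which pointed down. Ddx58, the cytosolic RNA sensor RIG-I, fell from 1016 ± 233 (SD, n = 2) to 146 ± 36.1 (SD, n = 4) units (log2 -2.68, adjusted p = 0.00271). It was the 1 called gene of 5 in the interferon response list, also when adjusted over the list alone (list adjusted p = 0.361). Of 6 sex chromosome genes, Xist, the RNA of X inactivation, was the 1 called, also when adjusted over the list alone (list adjusted p = 0.585). It fell from 460 and 276 units to 146, 98, 98 and 98 (log2 -1.59, adjusted p = 0.0122). The fibroblast genes were lower in the same lines, and the excess of Xist over the KO mean was smaller in WT replicate 2 than in WT replicate 1 by a log2 ratio of 1.08, inside the range of the 16 called fibroblast genes (0.61 to 2.19). Of the 791 genes called lower outside the fibroblast list, 24.5% lay inside this range. Among the 291 of them at least 2-fold lower it was 36.1%. Lying inside the range therefore does not show a fibroblast source.

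In ribosome biogenesis, the RNA modification and processing genes Dkc1 and Nop58 and the polymerase subunit gene Polr1c had log2 changes of -0.53, -0.28 and -0.52, and 18 of 21 members did not pass. The same 3 were lower when adjusted over the list alone, and the list reached an adjusted p of 0.241 with camera and 0.0348 with fry. Of 17 p53 targets, the exonuclease gene Aen fell by 0.34, and none was called when adjusted over the list alone. The list did not pass (adjusted p = 0.686), and its median (0.09) and mean (0.03) differ in sign from camera, which pointed down. None of 5 genes of the 2-cell stage passed over all genes, against 3 lower when adjusted over the list alone (list adjusted p = 0.164). Zscan4b, 1 of a family of near-identical copies, was at -1.39 (adjusted p = 0.08) and passed without WT replicate 1 (adjusted p = 0.0161) but in none of the other 5 fits with a library left out (adjusted p up to 0.337). Over the 6 fits its log2 change lay between -2.13 and -0.64. With a library left out, the call of Aen held in none of the 6 fits (adjusted p up to 0.114). Those of Peg12, Dkc1, Polr1c and Nop58 were lost in 3, 2, 5 and 5 of them, with adjusted p up to 0.091, 0.0667, 0.132 and 0.12.

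Whole chromosomes differed between libraries. Relative to WT replicate 1 and to all other chromosomes, the genes of chromosome 8 stood higher in WT replicate 2 (median log2 0.48, 95% bootstrap interval 0.43 to 0.51, 603 genes), KO line 2 (0.56), KO line 3 (0.55) and KO line 4 (0.50). KO line 1 lay at -0.001 (-0.03 to 0.04). Genes of chromosome 6 stood higher in KO line 4 alone (0.45, 0.41 to 0.50, 518 genes), with the other libraries between -0.03 and 0.01. The medians of the remaining 18 chromosomes, the Y chromosome left out, lay between -0.12 and 0.06. Of the genes on chromosomes 6 and 8, 13.1% and 13.3% were called, against 17.5% elsewhere, and a fit without their 1121 genes called 2013 genes.

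**Figure D4:**
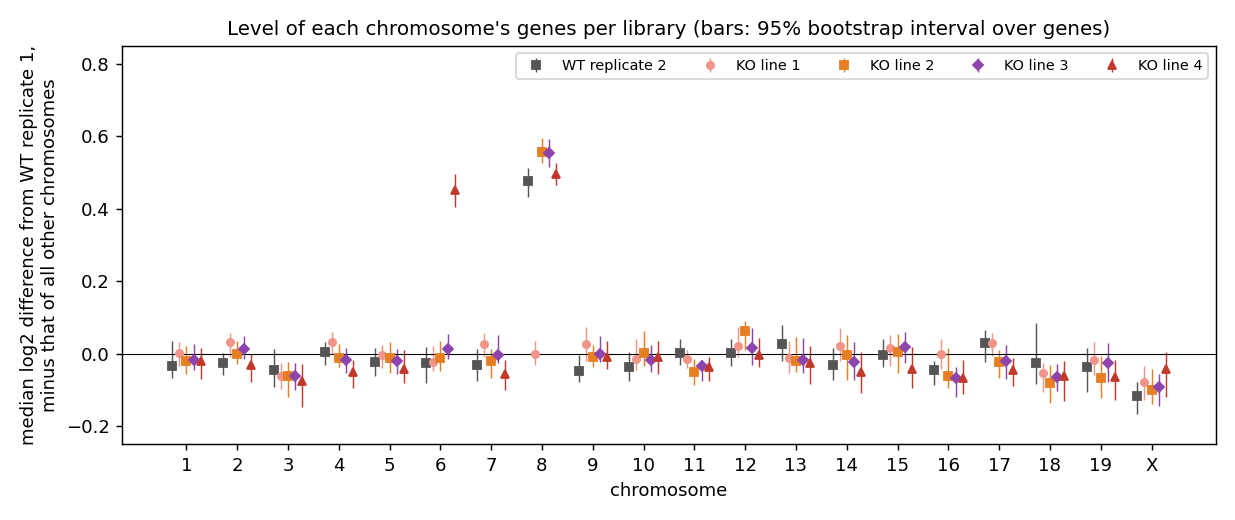
Median log2 difference from WT replicate 1 over the genes of each chromosome, minus that of all other genes (vertical axis), for WT replicate 2 and KO lines 1 to 4, with 95% bootstrap intervals over genes as bars. Chromosome 8 lies between 0.48 and 0.56 in 4 libraries and chromosome 6 at 0.45 in KO line 4, while the other values lie between -0.12 and 0.06.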

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

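In this part, the comparison with lists matched on GC content, length and level was set before its result was seen; the other tests named here were chosen after the results had been seen.

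For 2 of the 68 named genes with a spread among the KO lines, 1 line lay far from the other 3. Chance gives about 5%, so this count is not above chance. Rybp in KO line 4 was at 7682 units, and the gap to the nearest line took 0.869 of the range of the 4 lines on the log2 scale. Xist in KO line 1 was at 146 units against 98 in each of the other 3, so the gap took 1.0 of the range.

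The first pattern is the fall of fibroblast genes in the KO lines. With fewer of the same feeder fibroblasts in the KO libraries, each gene would follow the rest of the list among the 4 lines, and at least 3 genes with slopes bounded under 0.5 would argue against it; 2 of the 16 called genes (Col6a1 and Col6a2, at 4 to 8 units in the KO lines) had such slopes, 9 had slopes above 0.5, and 0.84% to 37.9% of the WT level was left. The slopes rest on 4 lines, with upper 95% bounds of up to 10.5, so this test could exclude little. If stem cells expressed none of these genes, a smaller share would leave the same percentage of each. The range found was 0.84% to 37.9%. A smaller share of feeder cells stays a candidate source that these slopes do not decide. Other fibroblasts or culture conditions in the WT libraries, and an effect of Ddx5 loss on these genes, stay open beside it and were not tested, because the design gives no WT library grown as a cloned line.

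The second pattern is the rise of germ line genes. Dilution of stem cell RNA by fibroblast RNA in the WT libraries would raise genes of stem cells alike, but the naive pluripotency list had a median log2 change of -0.031 and an upper quartile of 0.14, against 0.53 for 0.5 times the germ line median. A bias with GC content, transcript length or level is argued against by lists matched on these properties. Of 10000 such lists, 0 had a median as high (highest 0.6). This gave a resampling p of 0.0001, the smallest they can give, with genes drawn as independent. Drug selection and single-cell cloning of the KO lines were not tested apart from the loss of Ddx5, because WT cells are not labelled as cloned. A hypothesis is that the loss of Ddx5 itself raises germ line genes, which cloned WT lines or KO lines given Ddx5 back would part from cloning.

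The third pattern is the fall of ERK and Wnt target genes. Had fibroblast RNA in the WT libraries been the whole cause, the excess over the KO mean would be smaller in WT replicate 2 than in WT replicate 1 by the ratio found for the 18 fibroblast genes (log2 0.61 to 3.34), compared by rank for all members with an excess in at least 1 WT library. The 8 such Wnt genes differed from them (5 below that range and 1 above it, permutation p = 0.017, two-sided). Of the called ones, Bmp4 (-0.9), Notum (-1.33) and Znrf3 (0.44) lay below the range, and Axin2 (1.01) and Sp5 (0.89) inside it. Lying inside is common. Of the 291 genes outside the fibroblast list called at least 2-fold lower, 36.1% lay within the narrower range of the called fibroblast genes (0.61 to 2.19). Lef1, Tcf7 and Cdx1 also entered the test, though they were not called lower. The permutation treats genes as units and each ratio rests on 1 pair of WT libraries. It therefore does not settle the source for the set. For the 15 such ERK genes (7 below and 4 above; permutation p = 0.372) fibroblast RNA cannot be told apart from other sources, since the 7 called ones alone differed (exact permutation p = 0.000261) but calling favours genes with an excess in both WT libraries, and there are only 2 of these. Different strength of the kinase inhibitors between cultures, cloning and the loss of Ddx5 were not tested against each other.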

How the results depend on the processing

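The fits with 1 deposited unit as pseudocount, with a mean of at least 200 units, with the fibroblast level as a covariate and without chromosomes 6 and 8 were chosen after the data were seen. Ddx5 kept its direction and its call in all fits but that with the covariate (-2.53, adjusted p = 0.291). The count of 1878 genes stayed within 1.5 times itself for the other pseudocounts, filters, scalings and variance models and without chromosomes 6 and 8 (1428 to 2013); trimmed-mean scaling called 49.8% of its genes higher, against 57%. Leaving out single libraries gave 472 to 3304 genes, 331 to 1293 genes at least 2-fold changed and 41 to 54 of the 63 named calls; these fits have fewer libraries, and a lone WT library is assumed to vary as the KO lines do. Genes at least 2-fold changed numbered 436 with a pseudocount of 5 scaled units (48.4% higher) and 365 with a mean of at least 200 units, where fewer low genes enter, and with quantile normalization 47.0% of 639 were higher. With the replicate number as a block, 20 genes passed, all 20 at least 2-fold changed, and 6 named calls held; the block leaves 1 residual degree of freedom, the deviations of same-numbered libraries correlated at 0.145 and 0.097 across genes, and a WT replicate and a KO line share only a number. With the covariate, limma called 0 genes (2437 at an unadjusted p below 0.05), 0 at least 2-fold changed, 0 named genes and 0 lists. Of the covariate's variance 93.3% lies between WT and KO, and the SE of Ddx5 went from 0.317 to 1.27. Over the 59 named calls outside the fibroblast list, the median SE went from 0.262 to 0.908 and the median size of the log2 change from 1.87 to 1.56, with 20 at less than 0.5 times their size, as Axin2 (-1.67 to -0.09). Signs turned with it for Ddx4 (-0.33), Impact (0.22), Ndrg1 (-0.27), Nr0b1 (0.39), Prdm14 (-0.36), Sparc (0.39) and Xist (0.26), none past the threshold; the cause was not tested. Of the 5 lists passed by camera, 0 passed with an estimated correlation, and 4 with fry (glycolysis and hypoxia at 0.107), which also passed ribosome biogenesis (0.0348), 5 in all. Lists passed by camera numbered 4 to 6 with a library left out, 7 with the block, and 3 with a mean of at least 200 units, where ERK targets reached 0.0662 and the Wnt list had 4 genes left, too few to test. Dropping the filter, or asking for 5 scaled units, removed no gene. Depth is unknown, so its effect on low genes was not measured.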

Other observations

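The tests on gene families and on chromosome segments were chosen after the results had been seen; the limits for the segments were set with the segment values in view. The test for a chromosome gained or lost in a KO line was set before its result was seen.

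Among 178 gene families formed from the leading letters of symbols, with at least 8 measured members each, 2 held more lower genes than chance gives and 0 held more higher genes (Fisher's exact test, one-sided, 356 tests). In the collagen family (Col), 14 of 20 members fell, with a median log2 change of -2.43 (adjusted p = 1.4e-09). The fibroblast list holds 7 of these 20, and of the 13 outside it 7 fell and 1 rose. In the annexins (Anxa), calcium-dependent membrane-binding proteins, 5 of 9 members fell, with a median of -0.56 (adjusted p = 0.0404), in the same lines in which the fibroblast list was lower. The X-linked Xlr genes had the high median of 1.79 with 4 of 10 members higher, but the family did not pass (adjusted p = 0.734), and their near-identical copies may share reads, so members are not independent. Across genes, fold changes followed GC content with a Spearman rho of 0.0122 and transcript length with 0.131.

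A hypothesis from the chromosome levels is that some of these cultures carried an extra chromosome 8 or 6. The test for a gain or loss in a KO line looked for an autosome whose median lay more than 0.29 from the rest, and chromosome 6 in KO line 4 lay at 0.504 against the mean of the WT libraries, where a gain of 1 of 2 copies would give 0.58. Chromosome 8 also passed that limit in KO line 2 (0.324) and KO line 3 (0.305), with KO line 4 at 0.256 and KO line 1 at -0.251 against a mean that includes the higher WT replicate 2. Divided into 6 segments with equal numbers of genes, chromosome 8 stood 0.32 to 0.65 above WT replicate 1 in all 6 segments in WT replicate 2 and in KO lines 2, 3 and 4, and KO line 1 did not, as a gain of the whole chromosome would give. Chromosome 6 in KO line 4 stood 0.38 to 0.53 higher in all 6 segments, the other libraries within 0.29 of WT replicate 1. These values are consistent with trisomy 8 in 4 of the 6 libraries, 1 of them WT, and trisomy 6 in KO line 4, or with mixed cultures in which most cells carry them. Because the shift of chromosome 8 runs through both groups, it does not follow the loss of Ddx5. The level of Rybp in KO line 4, 7682 units against 5049 to 5335 in the other lines, may come from the same shift, since Rybp lies on chromosome 6. This was not tested. That Rybp passed without that line (log2 0.35, adjusted p = 0.0464, limma) concerns the other lines and does not show why KO line 4 was higher. No karyotype was analysed here.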
